A study of Macaca mulatta with 63 samples.

How the data were processed

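The series holds RNA sequencing of rhesus macaque (Macaca mulatta) tissues in 63 libraries. Transgenic animals (TG) carried copies of human MCPH1, a gene whose loss causes primary microcephaly, and wild-type animals (WT) did not. The authors' notes name Bowtie 0.12.2 and Cufflinks for all libraries and TopHat for the day 75 and fetal libraries. The genome build is not given in the sources used here. The authors deposited one value per gene and library in FPKM, fragments mapped to a gene scaled to its length and to the depth of the library. The files use 2 annotations: the day 75 and fetal files list 30246 genes and the layer files list 32386 genes, with 20572 identifiers shared. Symbols came from the files, and 1070 and 1184 further genes took a symbol from the reference table. The remaining 7531 and 9592 genes had none and stayed in the tests.

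All comparisons started from the deposited FPKM. Genes with a quantification status other than OK in any library of a comparison were left out of that comparison. Over all libraries of a data set such genes numbered 9 in the layers, 7 in the fetal tissues and 45 at day 75. That choice was made after the files were seen. FPKM were divided by a median-of-ratios factor per library, and log2 was taken after adding 1. Genes with a mean FPKM of at least 1 over the libraries of a comparison were tested with limma 3.58.1, with a mean-variance trend and Benjamini-Hochberg adjustment, two-sided, at adjusted p under 0.05. Layer comparisons held a term for embryonic day (E76 or E92). They held no term for sex, which by Y-linked genes was not balanced between TG and WT. Animal TG09 gave 2 libraries per layer, a plain and an md library. The labels do not say what md stands for, so the 2 libraries were averaged on the log scale and counted as 1 animal. The comparison of layers within WT paired the layers of an animal. The interaction tests compared the TG minus WT difference between layers or tissues within animals. Means and SDs are of FPKM as deposited, over animals and without the age term, and log2 differences are those of the fit to scaled values.

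Gene lists, 35 in all, were fixed before the data were examined: cell types of the developing cortex, cell cycle phases, MCPH1-related complexes, signalling, and markers of tissue carry-over and RNA quality. Lists with at least 5 measured genes were tested with camera in limma, with a preset correlation of 0.01, adjusted over the lists of a comparison. Of 205 list calls over the 17 tests, 0 held when the correlation between genes was estimated from the data, and 68 were also called in the same direction by fry, which asks whether a list moves on balance one way and called 98 lists in all. Each list is given with its count over all genes tested and its count adjusted over the list alone.

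Named genes followed a rule. Each test gives MCPH1, the 10 largest changes per direction among genes called with a symbol and with every test animal on the same side of the reference mean, and up to 4 members of a list with the smallest p. Not all genes the rule took are described. When no gene passed, the 5 smallest p per direction were taken as values. At day 75, with 1 TG animal, no test was run. Genes there were counted when TG02 lay more than 1 log2 unit from both WT animals, 8 per tissue and direction were named, and list medians were placed among 10000 random lists of equal size. The random lists were matched on expression level. Genes of a list can move together, so this place describes 1 animal and is no test. MCPH1 was also tested with a two-sided exact permutation of the animals, within 56 arrangements in the layers and 15 in the fetal tissues. The smallest p these allow are 0.018 and 0.067. The relation to WT age was Pearson's r across genes between the TG effect (0.4 times E76 plus 0.6 times E92) and the WT E92 minus E76 effect, against 30 exchanges of genotype within age.

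The comparisons, lists, thresholds and most alternatives were set before the files were examined. Alternatives set beforehand were FPKM as deposited, quantile scaling, a pseudocount of 0.1, no filter on low values, only the plain or only the md library of TG09, no age term, E92 animals only, embryonic day as a term in the fetal tissues, 1 fit per data set with animals as blocks, and leaving out 1 animal at a time. Some alternatives were chosen after seeing the data: leaving out the OSVZ or SVZ libraries of TG10 and TG11, pairs of WT libraries that stood apart, and the mean of CP and VZ alone. Where an alternative left 1 animal in a group, limma took the spread from the other animals, and the lone animal is assumed to vary like them. Values simulated with the spread of each fit, with known changes in 200 genes, were run through the same tests. At a difference of 1 log2 unit the changed genes recovered were 51 of 100 in CP, 52 in OSVZ, 56 in SVZ, 47 in VZ, 45 in fetal brain, 3 in fetal liver and 9 in fetal muscle, and at 2 log2 units 82, 88, 83, 91, 76, 54 and 65. The interaction tests recovered 20 of 100 for CP and VZ, 2 for fetal brain and liver and 1 for fetal brain and muscle at 1 log2 unit. At 2 log2 units they recovered 71, 43 and 48.

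No pair of libraries was identical. Deviations of an animal from its group mean were compared between its tissues. In a group of 2 animals both give the same value, which was counted once. Their r across genes had a median of 0.17 over 30 values in the layers (−0.26 to 0.39, 3 negative) and 0.18 over 15 in the fetal tissues (0.08 to 0.31). The negative values were of WT16 (−0.26) and WT17 (−0.14) between CP and VZ and of WT16 between OSVZ and VZ (−0.01). Genes are not independent replicates in these correlations. Work was done in R 4.3.3 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.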

Results

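RNA levels were measured in 3 sets of rhesus macaque tissue. The layer set held 36 libraries from laser-captured fetal cortex. It covered the cortical plate (CP, where neurons settle), the outer subventricular zone (OSVZ), the subventricular zone (SVZ) and the ventricular zone (VZ), the last 3 being zones of progenitors. These came from 3 TG animals (TG09 at embryonic day 76, TG10 and TG11 at embryonic day 92) and 5 WT animals (WT13 and WT14 at E76, WT15, WT16 and WT17 at E92). The fetal set held 18 libraries of brain, liver and muscle from 2 TG animals (TG03 and TG04, both E136) and 4 WT animals (WT09 at E140, WT10 at E130, WT11 at E145, WT12 at E135). The day 75 set held 9 libraries of the same 3 tissues from TG02, WT04 and WT05. The depth implied by the files was 5 to 11.1 M fragments per layer library, 4.79 to 9.07 M per fetal library and 6.13 to 9.36 M per day 75 library. Between 10184 and 12590 genes reached 1 FPKM in a layer library, 11018 to 13636 in a fetal library and 13124 to 15687 in a day 75 library.

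MCPH1 (ENSMMUG00000010137, a regulator of chromosome condensation and the DNA damage response) was the gene the transgene adds. It lies on chromosome 8, at 6572395 to 6809706 in the annotation of the layers and 6469408 to 6705742 in that of the other tissues. In fetal brain its level was 24.6 ± 23.1 FPKM (SD, n = 2) in TG and 3.19 ± 0.41 (SD, n = 4) in WT. In fetal liver it was 38.2 ± 49.2 (n = 2) against 1.28 ± 0.255 (n = 4), and in fetal muscle 203 ± 255 (n = 2) against 1.39 ± 0.224 (n = 4). Both TG animals lay above all 4 WT animals in each tissue, with a two-sided exact permutation p = 0.0667, the smallest the 15 arrangements allow. TG04 held more than TG03: 40.9 and 8.31 FPKM in brain, 72.9 and 3.37 in liver, 383 and 22.8 in muscle. At day 75, TG02 held 60.2 FPKM in brain, 35.2 in liver and 1217 in muscle. The WT animals there held 2.94 and 2.72 in brain, 2.19 and 2.45 in liver, and 2.07 and 2.89 in muscle. The limma adjusted p for the fetal tissues were 0.16 in brain, 0.469 in liver and 0.0647 in muscle, with log2 differences of 2.31, 3.14 and 5.38.

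In the layer libraries labelled transgenic, MCPH1 was not above WT. Its level was 2.75 ± 0.898 FPKM (SD, n = 3) against 2.91 ± 1.8 (SD, n = 5) in CP, 2.91 ± 0.666 against 4.31 ± 0.789 in OSVZ, 3.07 ± 0.803 against 4.66 ± 1.13 in SVZ and 2.93 ± 0.808 against 3.77 ± 0.723 in VZ. The log2 differences without an age term were 0.01, −0.15, −0.23 and −0.01, with two-sided exact permutation p = 1, 0.232, 0.321 and 0.893. None of the 3 TG animals lay above all WT animals in any layer. In FPKM as deposited TG10 and TG11 lay below every WT animal in OSVZ (2.35 and 2.73 against 3.51 or more), SVZ (2.58 and 2.63 against 3.15 or more) and VZ (2.63 and 2.32 against 2.76 or more), and the median gene there shifted by −0.319, −0.269 and −0.307 log2. On scaled values only TG11 in OSVZ did (2.01 log2 against 2.04 or more). The upper 95% bounds of the limma difference, with the age term, were 0.59 log2 in CP, 0.18 in OSVZ, 0.17 in SVZ and 0.32 in VZ. The sign in CP turned with quantile scaling (−0.15) and with the plain libraries of TG09 alone (−0.04), and in VZ with the plain libraries (0.04). It also turned in CP without TG09 (−0.15), WT15 (−0.16) or WT16 (−0.16), and in VZ it was 0 without TG10, 0.02 without TG11 and 0.05 without WT14.

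**Figure D1:**
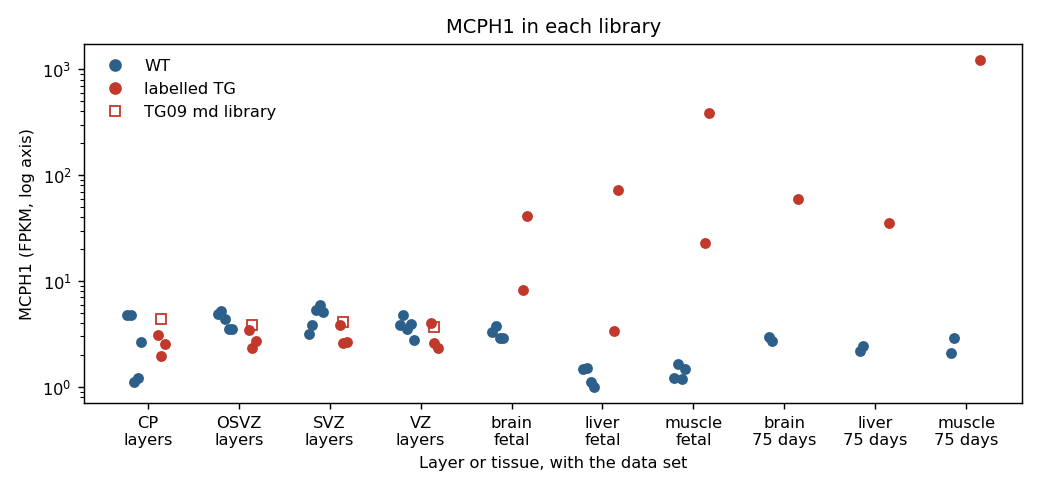
MCPH1 in FPKM on a log axis for each library, by tissue, layer and genotype, with open squares for the md libraries of TG09. TG03, TG04 and TG02 lie above every WT library of their tissues, and no layer library labelled TG lies above every WT library of its layer.

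The OSVZ comparison asked how the outer progenitor zone differed between animals labelled TG and WT. MEF2C (ENSMMUG00000019836), a neuronal transcription factor, rose by 2.78 log2 to 118 ± 84.8 FPKM (SD, n = 3) from 13.6 ± 8.47 (SD, n = 5). RPRM (ENSMMUG00000022529), which can arrest cells in G2, rose by 3.74 log2 to 138 ± 162 from 5.50 ± 2.2, and ADCY1, a calcium-stimulated adenylyl cyclase, by 3.24 log2 to 56.2 ± 40.8 from 4.97 ± 5.18. HOPX (ENSMMUG00000017788), a marker of outer radial glia, fell by 2.48 log2 to 47.5 ± 53 from 214 ± 65.7. PTN, a growth factor of these cells, fell by 2.48 log2 to 252 ± 275 from 1146 ± 282, and PPP1R17, found in intermediate progenitors, by 2.43 log2 to 10.6 ± 14.7 from 39.2 ± 23.5. IGSF21 (3.26 log2), CALN1 (3.07), C1orf95 (3.06), RIMS4 (2.97), LRFN2 (2.82), KCTD12 (2.81) and ND3 (2.79) also rose. MGST1 (−2.42 log2), IL33 (−2.55), C15orf41 (−2.57), MOXD1 (−2.69) and C19H19orf81 (−3.38) fell, and DLEU1_1 and SEM1 were listed at 0 in all TG animals. The limma adjusted p of these genes lay between 0.00867 and 0.0493. All of them lay on the same side of the WT mean in 3 of 3 TG animals, as the rule for naming required. For C19H19orf81 this holds against the mean of both ages alone: it was at 0 in WT at E76, and TG09 differed from WT of its age by 0 log2.

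By list, 26 of 35 genes of G2 to M phase fell over all genes tested and 33 fell adjusted over the list alone, among them CCNB2 (−1.86 log2), BUB1 (−1.5) and NUF2 (−1.48). The list median was −1.11 log2 (camera adjusted p = 3.22e-12; adjusted p = 0.577 with an estimated correlation). Of 29 genes of G1 to S phase 16 fell, and 19 adjusted over the list alone, with PCNA at −1.45 and MCM3 at −1.27 (camera adjusted p = 8.99e-08; adjusted p = 0.577 with an estimated correlation). Of 14 outer radial glia genes 9 fell, and 11 adjusted over the list alone, including BMP7 (−1.48) and PEA15 (−1.57), with a median of −1.24 (camera adjusted p = 3.16e-06; adjusted p = 0.577 with an estimated correlation). Of 18 radial glia genes 7 fell, and 9 fell and 1 rose adjusted over the list alone, with PAX6 at −1.81 and SLC1A3 at −1.83 (camera adjusted p = 0.0044; adjusted p = 0.577 with an estimated correlation). Of 15 intermediate progenitor genes 5 fell, and 8 adjusted over the list alone, with NHLH1 at −2.14 and NEUROD4 at −2.02 (camera adjusted p = 0.002; adjusted p = 0.577 with an estimated correlation). Of 44 synaptic genes 20 rose and 2 fell, and 29 rose and 2 fell adjusted over the list alone, with SHANK1 at 2.35 and GRIN2B at 2.08 and a median of 1.21 (camera adjusted p = 1.68e-08; adjusted p = 0.577 with an estimated correlation). Of 26 genes of newborn and migrating neurons 10 rose and 1 fell, and 16 rose and 1 fell adjusted over the list alone, with NEFM at 2.72 and NRN1 at −1.32 (camera adjusted p = 6.45e-05; adjusted p = 0.577 with an estimated correlation). Of 12 upper layer neuron genes 4 rose, and 8 adjusted over the list alone, including MEF2C (2.78) and RORB (1.68) (camera adjusted p = 0.00626; adjusted p = 0.577 with an estimated correlation).

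Lists of genes close to MCPH1 in function were also tested in OSVZ. Of 23 primary microcephaly genes 6 fell, and 7 adjusted over the list alone, with MFSD2A at −1.05 and LMNB1 at −0.82 log2 (camera adjusted p = 0.0044; adjusted p = 0.577 with an estimated correlation). Of 8 condensin subunits, which fold mitotic chromosomes, 3 fell, and 5 adjusted over the list alone, with NCAPG at −1.30 and NCAPH at −0.91 (camera adjusted p = 0.019; adjusted p = 0.577 with an estimated correlation). Of 20 DNA damage response partners of MCPH1 5 fell, and 5 adjusted over the list alone, with RPA2 at −1.01 and BRCA1 at −0.91 (camera adjusted p = 0.00971; adjusted p = 0.577 with an estimated correlation). Without the OSVZ libraries of TG10 and TG11, which leaves TG09 alone against 5 WT animals, these 3 calls ended: the median was −0.1 for primary microcephaly genes (camera adjusted p = 0.361), −0.3 for condensin subunits (0.316) and −0.22 for DNA damage response partners of MCPH1 (0.163). These libraries stood apart in several groups. RPRM was at 62.4 and 324 FPKM in TG10 and TG11, at 50.9 and 4.42 in the plain and md libraries of TG09 and at 3.36 to 8.63 in WT. MKI67, a proliferation marker, was at 2.19 and 0.687 FPKM in TG10 and TG11, at 14.2 and 21.1 in TG09 and at 5.53 to 23.0 in WT. Their median Spearman correlations with the other OSVZ libraries were 0.782 and 0.812. The OSVZ library of TG10 also had the lowest implied depth of the layer set (5 M fragments). Its mitochondrial share of FPKM was 2.05%, against 0.4% in TG11 and 0.13 to 0.85% in the WT OSVZ libraries. In the plain OSVZ library of TG09 the median of 11 ventral forebrain genes was 1.63 log2 above that of its md library, and that of 7 cortical genes differed by −1.87.

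In OSVZ, limma called 2673 of 12128 genes, 1466 higher and 1207 lower. The count was 6 without the OSVZ libraries of TG10 and TG11, an alternative chosen after seeing the data, 3 with the md library of TG09 alone, 889 without the age term and 1025 without the filter. The fit without TG10 and TG11 has 1 TG animal, TG09, which is assumed to vary like the WT animals, so its count and p values rest on 1 animal against 5. It was 1 without TG10, 2 without TG11, 7 without WT14, 1190 without WT15, 0 without WT16 (4013 genes at unadjusted p under 0.05) and 6 without WT17. Without those libraries of TG10 and TG11 the medians were −0.53 log2 for G2 to M phase (camera adjusted p = 7.58e-06), −0.71 for outer radial glia (4.15e-05), 0.63 for synapse and synaptic signalling (0.00352), and these calls ended: 0.32 for newborn and migrating neurons (0.294), −0.1 for radial glia (0.294) and 0.12 for upper layer neurons (0.154). The mean of the synapse and synaptic signalling list in OSVZ was 3.98 log2 in the plain library of TG09 and 2.82 in its md library, against 2.93 and 2.65 in WT13 and WT14, so the md library lay between these 2 WT animals.

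**Figure D2:**
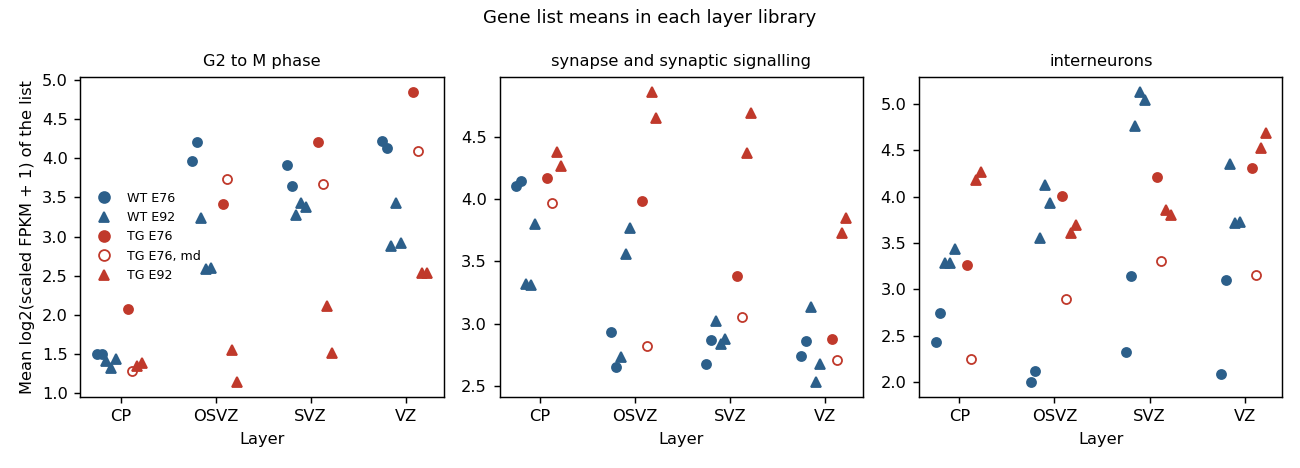
Mean log2 scaled FPKM of 3 gene lists (G2 to M phase, synapse and synaptic signalling, interneurons) for each layer library, by genotype, with circles for E76, triangles for E92 and open marks for the md libraries of TG09. The medians of TG minus WT in OSVZ were −1.11 for G2 to M phase and 1.21 for synaptic genes.

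In SVZ, the zone between OSVZ and VZ, TG and WT were compared in the same way. GRIN1 (ENSMMUG00000001661), the obligate NMDA receptor subunit, rose by 3.36 log2 to 27.9 ± 21.7 FPKM (SD, n = 3) from 1.10 ± 0.343 (SD, n = 5). NRGN, a postsynaptic calmodulin-binding protein, rose by 3.54 log2 to 96.1 ± 85.8 from 4.38 ± 2.82, CAMK2B, a neuronal kinase, by 3.30 log2 to 40.2 ± 32.3 from 2.07 ± 0.615, and RPRM by 4.47 log2 to 148 ± 137 from 3.67 ± 2.6. ADCY1 (3.55 log2), ARHGDIG (3.37), CALY (3.22), PSD (3.2) and EEF1A2 (3.12) rose, and CALN1 was at 10.1 ± 5.36 in TG and listed at 0 in all WT. BTG1 (ENSMMUG00000040920), an antiproliferative factor, fell by 1.69 log2 to 47.6 ± 31.9 from 168 ± 51. C6orf226 (−2.40 log2), TUG1_3 (−2.39), HIST2H2BE (−1.82), MPC2 (−1.71), PCLAF (−1.64), SDHD (−1.64), UCP2 (−1.61), MMP24OS (−1.59) and CENPV (−1.59) fell. These genes moved the same way in 3 of 3 TG animals, as the rule for naming required, at limma adjusted p between 0.021 and 0.0438.

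Of 42 synaptic genes in SVZ 24 rose, and 32 adjusted over the list alone, including SHANK1 (2.32 log2), GRM5 (1.83) and CPLX2 (340 ± 109 FPKM against 151 ± 30.1). The list median was 1.17 (camera adjusted p = 2.28e-12; adjusted p = 0.722 with an estimated correlation). Of 35 genes of G2 to M phase 0 passed limma over all genes tested and 27 fell adjusted over the list alone, with a median of −0.99 (camera adjusted p = 1.36e-08; adjusted p = 0.722 with an estimated correlation). KIF20A stood at −1.21 log2 (adjusted p = 0.0542 over all genes). Of 15 intermediate progenitor genes 1 fell, BTG2 at −1.10, and 8 fell adjusted over the list alone (camera adjusted p = 0.00426; adjusted p = 0.401 with an estimated correlation). Of 10 oligodendrocyte precursor genes 3 rose, and 4 adjusted over the list alone, with OLIG1 at 1.80, CSPG5 at 1.61 and OLIG2 at 1.22 (camera adjusted p = 0.0282; adjusted p = 0.722 with an estimated correlation). Of 16 endothelial and pericyte genes 6 fell, and 8 adjusted over the list alone, with COL4A1 at −0.77 and CDH5 at −0.76 (camera adjusted p = 0.00304; adjusted p = 0.399 with an estimated correlation). Of 7 genes of meninges and fibroblasts 4 fell, and 4 adjusted over the list alone, with DCN at −1.53 and FN1 at −0.60 (camera adjusted p = 0.0282; adjusted p = 0.401 with an estimated correlation). MKI67 was at 2.55 and 1.20 FPKM in the SVZ of TG10 and TG11 and at 9.49 to 13.1 in WT15, WT16 and WT17. NKX2-1, a factor of the ventral forebrain, was at 83.4 FPKM in the plain SVZ library of TG09 and 1.31 in its md library.

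In SVZ, limma called 1267 of 12036 genes, 806 higher and 461 lower. The count was 2903 with FPKM as deposited, 530 without the filter, 2309 with the plain and 0 with the md libraries of TG09 (3931 at unadjusted p under 0.05), 27 without the age term, 5978 at E92 alone, 1995 in the blocked fit and 4 without the SVZ libraries of TG10 and TG11, which leaves 1 TG animal, TG09, assumed to vary like the WT animals. It was 5524 without TG09, 0 without TG10, WT15 or WT16 (3009, 3101 and 3100 genes at unadjusted p under 0.05), 2 without TG11 and 1 without WT17. In that fit of 1 animal against 5, chosen after seeing the data, the median of synapse and synaptic signalling was 0.46 log2 (camera adjusted p = 0.000109) and that of G2 to M phase turned to 0.13 (camera adjusted p = 0.0293). The call of oligodendrocyte precursors ended there (0.3, camera adjusted p = 0.166), as did that of meninges and fibroblasts (−0.44, 0.072). At E92 alone the calls of intermediate progenitors (0.1) and of endothelial cells and pericytes (0.0741) ended.

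In VZ, where radial glia line the ventricle, the same question was asked. VIM (ENSMMUG00000003193), the intermediate filament of radial glia, fell by 1.55 log2 to 336 ± 264 FPKM (SD, n = 3) from 954 ± 173 (SD, n = 5). HES1, a Notch target that maintains progenitors, fell by 1.58 log2 to 25.6 ± 23.8 from 81.8 ± 51.4, and FGFR3, a growth factor receptor, by 1.83 log2 to 38.6 ± 38.4 from 141 ± 66.7. OLIG2 (ENSMMUG00000017652), a factor of the oligodendrocyte lineage, rose by 1.99 log2 to 28.2 ± 0.728 from 8.08 ± 5.56, OLIG1 by 2.10 log2 to 21.9 ± 3.63 from 4.75 ± 2.98, and DLX6, an interneuron factor, by 1.95 log2 to 12.3 ± 1.31 from 2.70 ± 1.69. GNG8 (2.16 log2), FAM84A (1.67), VSTM2L (1.51), SYT6 (1.5), GRIK3 (1.41), CCDC88A (1.39) and TGFA (1.35) rose. MFAP4 (−2.27 log2), FEZF2 (−1.66), CYR61 (−1.63), IGFBP7 (−1.62), KCNG1 (−1.51), SDHD (−1.41) and LRRC10B (−1.41) fell. All moved the same way in 3 of 3 TG animals, as the rule for naming required, at limma adjusted p between 0.0238 and 0.0465. TG09 entered here as the mean of its plain and md libraries.

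Of 18 radial glia genes in VZ 3 fell, VIM, HES1 and LHX2 (−1.08 log2), and 9 fell and 1 rose adjusted over the list alone, with a median of −0.91 (camera adjusted p = 9.71e-06; adjusted p = 0.101 with an estimated correlation). Of 16 astrocyte genes 2 fell, FGFR3 and CLU (323 ± 47.3 FPKM against 873 ± 251), and 6 adjusted over the list alone (camera adjusted p = 0.00178; adjusted p = 0.588 with an estimated correlation). With the md library of TG09 alone the median of astrocytes was −0.29 (camera adjusted p = 0.0827). Of 10 oligodendrocyte precursor genes 2 rose, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00499; adjusted p = 0.353 with an estimated correlation). Of 17 interneuron genes 1 rose, DLX6, and 2 adjusted over the list alone, with a median of 0.73 (camera adjusted p = 0.000136; adjusted p = 0.588 with an estimated correlation). Of 36 synaptic genes 0 passed limma over all genes and 14 rose adjusted over the list alone, with a median of 0.62 (camera adjusted p = 8.15e-08, and adjusted p = 0.588 with an estimated correlation). The list mean was 3.73 and 3.85 log2 in TG10 and TG11, against 2.53 to 3.13 in WT of their age. In TG09 it was 2.88 (plain) and 2.71 (md), against 2.74 and 2.86 in WT13 and WT14, so the rise rested on TG10 and TG11. Of 26 newborn neuron genes 0 passed limma over all genes and 9 rose adjusted over the list alone, with a median of 0.66 (camera adjusted p = 2.32e-06; adjusted p = 0.588 with an estimated correlation). NKX2-1 stood at 389.9 FPKM in the plain VZ library of TG09 and 1.81 in its md library, and NEUROD2, a factor of cortical excitatory neurons, at 0.173 and 27.3. DLX6 stood at 25.67 and 1.525 FPKM in the same 2 libraries and OLIG2 at 50.53 and 7.283, with 12.41 and 10.97 for DLX6 and 28.12 and 27.45 for OLIG2 in TG10 and TG11. In FPKM the md values of both genes lay below their WT means, so the place of TG09 above those means rests on its plain library. The small SDs of both genes in TG come from averaging the 2 libraries of TG09. TTR, a marker of choroid plexus, was at 327 FPKM in the VZ of WT13 and 123 in that of WT14, and at most 1.48 in the other VZ libraries.

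In VZ, limma called 76 of 12521 genes, 23 higher and 53 lower. The count was 1028 with FPKM as deposited, 26 with quantile scaling, 23 without the filter, 797 with the plain libraries of TG09, 245 in the blocked fit, 0 with its md libraries and 0 without the age term (1813 and 2039 genes at unadjusted p under 0.05). It was 778 without TG09, 47 without WT15, 42 without WT16 and 0 without TG10, TG11, WT13, WT14 or WT17 (1800, 1515, 2534, 2660 and 2052 genes at unadjusted p under 0.05).

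In CP, few genes passed. SDHD (ENSMMUG00000015247), a subunit of succinate dehydrogenase, fell by 1.56 log2 to 5.98 ± 0.411 FPKM (SD, n = 3) from 17.9 ± 2.22 (SD, n = 5), at limma adjusted p = 0.0324. AIF1L (ENSMMUG00000042881) rose by 1.41 log2 to 4.49 ± 0.965 from 0.805 ± 0.374, at adjusted p = 0.0387. Each moved the same way in 3 of 3 TG animals, as the rule for naming required. The signal recognition particle RNA Metazoa_SRP was at 12.6 ± 8.97 in TG and listed at 0 in all WT. Of 14 interneuron genes 0 passed limma over all genes, and 11 rose and 1 fell adjusted over the list alone, with a median of 0.89 (camera adjusted p = 0.00014; adjusted p = 0.541 with an estimated correlation). SP9, an interneuron factor, stood at 1.16 log2 (adjusted p = 0.0957). The mean of the interneurons list in CP was 3.26 log2 in the plain library of TG09 and 2.25 in its md library, against 2.43 and 2.75 in WT13 and WT14, and ventral forebrain genes there had a median 1.26 log2 higher in the plain than in the md library. It was 4.18 and 4.26 in TG10 and TG11, against 3.28 to 3.44 in WT of their age. Of 38 cytosolic ribosomal protein genes 0 passed limma and 0 passed adjusted over the list alone, with a median of −0.72 (camera adjusted p = 1.6e-07; adjusted p = 0.577 with an estimated correlation). That median was −0.16 with quantile scaling (camera adjusted p = 0.0669) and −0.23 without the CP libraries of WT15 and WT16. These 2 libraries had median Spearman correlations of 0.834 and 0.848 with the other CP libraries.

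In CP, limma called 6 of 11237 genes, 4 higher and 2 lower, 3 of them without a symbol, with 3245 at unadjusted p under 0.05. The count was 2 with quantile scaling, with the smaller pseudocount or without the age term, 1656 with the plain libraries of TG09, 1525 at E92 alone and 1348 in the blocked fit. It was 0 without the filter, with the md libraries and without the CP libraries of WT15 and WT16 (4146, 2038 and 2330 genes at unadjusted p under 0.05). It was 2601 without TG09, 2 without WT13 or WT14, 1 without TG11, WT15 or WT17, and 0 without TG10 or WT16 (1450 and 2348 genes at unadjusted p under 0.05).

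Over the mean of the 4 layers, CPLX2, which controls vesicle release, rose by 2.36 log2 to 502 ± 72.7 FPKM (SD, n = 3) from 170 ± 135 (SD, n = 5). Against WT of the same age it differed by 0.51 log2 in TG09, 3.37 in TG10 and 3.41 in TG11. The WT animals of E92 include WT15 and WT16, whose CP libraries stood apart. B2M, the shared chain of MHC class I, fell by 1.43 log2 to 22.8 ± 5.63 from 71.0 ± 14.4, and SDHD by 1.76 log2 to 13.1 ± 10.2 from 46.7 ± 17.3. ND3 (2.85 log2), RPRM (2.43), ADCY1 (2.38), CALN1 (2.26), Metazoa_SRP (2.26), U2 (2.09), RIMS4 (2.07), KCTD12 (2.05) and IRGQ (2.04) also rose. SEM1 (−4.70 log2), SNRPG (−2.01), LINC01420 (−1.88), MMP24OS (−1.56), IGFBP7 (−1.52), MPC2 (−1.44), RPS29 (−1.44) and RNASE1 (−1.43) fell. These genes moved the same way in 3 of 3 TG animals, as the rule for naming required, at limma adjusted p between 0.00766 and 0.0414. Of 44 synaptic genes 32 rose, and 33 rose and 1 fell adjusted over the list alone, with a median of 0.83 (adjusted p = 0.684 with an estimated correlation). Of 35 genes of G2 to M phase 15 fell, and 24 adjusted over the list alone, with a median of −0.57 (adjusted p = 0.684 with an estimated correlation). The mean of this list in TG09 (plain, md) was 3.42 and 3.73 log2 in OSVZ, against 3.96 and 4.21 in WT13 and WT14. It was 4.21 and 3.67 against 3.92 and 3.65 in SVZ, and 4.85 and 4.09 against 4.22 and 4.13 in VZ. In CP it was 2.07 and 1.29 against 1.5 in both. Only in OSVZ did both TG09 libraries lie below both WT animals of that age, so the fall leaned on TG10 and TG11.

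Over the 4 layers together, limma called 3283 of 12328 genes, 1773 higher and 1510 lower. The count was 344 over CP and VZ alone, 9 with the md libraries of TG09, 2040 without the filter, 1083 without the age term and 5095 at E92 alone. It was 5326 without TG09, 394 without TG10, 210 without TG11, 1594 without WT15, 1082 without WT16 and 1761 without WT17. With FPKM as deposited the median gene shifted by −0.319 log2 in OSVZ, −0.269 in SVZ, −0.307 in VZ and −0.208 over the 4 layers, and 23%, 22.4%, 5.1% and 22.6% of called genes were higher in TG. With scaling those shares were 54.8%, 63.6%, 30.3% and 54%.

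A test of whether the TG minus WT difference itself differed between CP and VZ called 0 of 12414 genes in limma, with 2224 at unadjusted p under 0.05. On simulated values this test recovered 20 of 100 changed genes at 1 log2 unit, so many differences of that size could be missed. The largest candidates were FGFR3 (2.38 log2) and CDH4 (2.31) toward CP and NPY, an interneuron peptide (−5.20), and EDIL3 (−1.87) toward VZ, at adjusted p between 0.139 and 0.14. CNKSR3 (1.75), LRRC10B (1.71), CNN2 (1.27), RNASE1 (−1.63), KCNF1 (−1.5) and FAM84A (−1.39) followed. Of 18 radial glia genes 0 passed over all genes and 13 rose adjusted over the list alone, with a median difference of 1.17 (adjusted p = 0.0697 with an estimated correlation). The count was 69 with the plain libraries of TG09 and 406 without TG09.

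The series title speaks of prolonged, human-like development, so the TG minus WT difference was set beside the change with age in WT. Across genes, Pearson's r was −0.56 in CP (Spearman's rho −0.52), 0.13 in OSVZ (0.13), −0.09 in SVZ (−0.12), −0.1 in VZ (0) and −0.14 over the 4 layers (−0.1). Genes are not independent replicates, so p came from 30 exact permutations of genotype within age: 0.233, 0.633, 0.767, 0.667 and 0.667, all 0.767 after adjustment over the 5. With the md library of TG09 alone, r in CP was −0.6 (exact permutation p = 0.0333, unadjusted and the smallest the 30 permutations allow). Leaving out 1 animal gave −0.7 to −0.47 in CP, and the sign turned in OSVZ without TG09 (−0.08) and in SVZ without WT14 (0.03). The CP libraries of WT15 and WT16, which stood apart, entered both the age effect and the WT reference of the TG effect. Leaving out 1 animal always keeps at least 1 of them, so the range in CP does not show r without both. With both CP libraries left out, which leaves WT17 as the only E92 WT animal, r in CP kept its negative sign.

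The comparison of E76 and E92 in WT asked which genes change with age. In SVZ, NEUROG2 (ENSMMUG00000014078), which drives excitatory neurogenesis, fell by 3.50 log2 to 8.56 ± 5.83 FPKM (SD, n = 3) from 103 ± 2.96 (SD, n = 2). GAD2, a GABA-synthesising enzyme, rose by 3.48 log2 to 43.0 ± 9.41 from 3.46 ± 2.29, and NPY by 4.13 log2 to 100.2 ± 44.8 from 4.96 ± 1.54. CRABP1 (4.23 log2), NKX2-1 (4.00), DLX6 (3.74), SP9 (3.35) and MCPH1 (0.62, to 5.44 ± 0.401 from 3.49 ± 0.477, adjusted p = 0.0205) rose, and TTR (−5.19), NEUROD6 (−4.53), NHLH1 (−2.92), NEUROG1 (−2.82) and PRDM8 (−2.77) fell. In the other layers MCPH1 stood on the other side of 0, at −1.06 log2 in CP (adjusted p = 0.0556), −0.28 in OSVZ (0.259) and −0.225 in VZ (0.59). Of 17 interneuron genes 14 rose, and 15 adjusted over the list alone (camera adjusted p = 2.47e-07; adjusted p = 0.671 with an estimated correlation). Of 15 intermediate progenitor genes 10 fell and 1 rose, and 11 fell and 2 rose adjusted over the list alone, with a median of −1.25 (adjusted p = 0.671 with an estimated correlation).

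In OSVZ, APOE, the lipid carrier of glia, rose with age by 2.92 log2 to 826 ± 221 FPKM (SD, n = 3) from 115 ± 38.1 (SD, n = 2). SPARCL1, secreted by astrocytes, rose by 3.10 log2 to 103 ± 5.82 from 12 ± 3.1, and NEUROG2 fell by 2.08 log2 to 19.9 ± 8.86 from 87.4 ± 3.02. S100A1 (3.78 log2), OLIG1 (2.94) and ALDH1A1 (2.93) rose, and PARP8 (−4.45), NEUROD6 (−2.78), UBE2C (−2.37) and FZD7 (−2.10) fell. Of 35 genes of G2 to M phase 5 fell, and 34 adjusted over the list alone, with a median of −1.28 (camera adjusted p = 2.11e-18; adjusted p = 0.446 with an estimated correlation). Of 16 interneuron genes 9 rose, and 14 adjusted over the list alone, with a median of 1.82 (camera adjusted p = 2.37e-10; adjusted p = 0.175 with an estimated correlation).

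In CP, CCK, a neuropeptide, rose with age by 3.53 log2 to 138 ± 44.8 FPKM (SD, n = 3) from 12 ± 3.91 (SD, n = 2). DCX, a microtubule protein of migrating neurons, fell by 4.59 log2 to 5.36 ± 7.26 from 107 ± 14.7, and CPLX2 by 4.31 log2 to 15.2 ± 18.2 from 228 ± 11.8. For both genes the SD at E92 exceeded the mean. The E92 group holds the CP libraries of WT15 and WT16, which stood apart. Their median Spearman correlations with the other CP libraries were 0.834 and 0.848, against 0.904 for WT17, so the E92 means in CP lean on these libraries. NTS (3.69 log2), S100A1 (3.44), CRH (3.37) and NDUFA11 (3.28) rose, and GNG2 (−7.40), EPHA3 (−3.89), CACNA2D1 (−3.64) and RUNX1T1 (−3.58) fell. Of 23 axon guidance genes 12 fell and 1 rose, and the same numbers adjusted over the list alone, with a median of −1.02 (adjusted p = 0.564 with an estimated correlation). Of 38 ribosomal protein genes 9 rose, and 11 adjusted over the list alone, with a median of 1.13 (adjusted p = 0.567 with an estimated correlation). In VZ, GSX2, a ventral progenitor factor, rose by 2.88 log2 to 7.57 ± 1.91 FPKM (SD, n = 3) from 0.179 ± 0.254 (SD, n = 2). FBXO2 (3.52 log2), AGT (2.69), PPP2R2C (2.63) and MMRN1 (1.96) rose, and TTR (−6.64), HAUS1 (−2.28), MSTN (−2.06) and CDON (−2.06) fell.

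With age, limma called 2222 of 11105 genes in CP (931 higher, 1291 lower), 299 of 12062 in OSVZ (163, 136), 3361 of 11868 in SVZ (1665, 1696) and 30 of 12554 in VZ (16, 14), with 3 animals against 2. The count in CP was 13 without the filter and 19 without the CP libraries of WT15 and WT16, in SVZ 12 without those of WT16 and WT17, and in VZ 0 without those of WT16 and WT17 (2572 genes at unadjusted p under 0.05). Each fit without 2 WT animals sets 1 E92 animal against 2 at E76, and assumes that it varies like them. Mitochondrial and small RNA genes were among the largest changes with age. MT-ND6 rose by 5.68 log2 in CP, 6.52 in OSVZ, 5.80 in SVZ and 5.33 in VZ, and MT-CO2 by 4.55 in CP, 4.15 in OSVZ and 3.57 in VZ. ND3 fell in CP (−5.38) and SVZ (−4.01), and genes named U3 fell in all 4 layers (−4.34 to −6.78). Entries named 5_8S_rRNA, not taken to be the same gene in both layers, were listed at 0 in E92. In E76 they were at 8711 ± 9000 FPKM in CP and 3294 ± 1410 in VZ (ENSMMUG00000044293).

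Within WT, CP and VZ differed by known markers of neurons and progenitors. NEUROD6 (ENSMMUG00000022699), a factor of excitatory neurons, was higher in CP by 6.41 log2, at 566 ± 58.8 FPKM (SD, n = 5) against 20.9 ± 26.2 (SD, n = 5), and MEF2C by 5.81 log2, at 274 ± 78.3 against 5.84 ± 1.39. SFRP1, a Wnt antagonist, was lower in CP (−5.73 log2), at 2.57 ± 0.795 against 291 ± 172, and so was ID4 (−5.18 log2), at 7.19 ± 3.61 against 385 ± 58.4. Of 35 genes of G2 to M phase 34 were lower in CP (adjusted p = 0.305 with an estimated correlation), as were 14 of 14 outer radial glia genes and 15 of 15 astrocyte genes (adjusted p = 0.0617 with an estimated correlation for each). The same numbers passed adjusted over the list alone. Of 26 newborn neuron genes 18 were higher and 4 lower, over all genes and adjusted over the list alone (adjusted p = 0.204 with an estimated correlation). In OSVZ against VZ, CRYAB, a small heat shock protein, was lower (−5.79 log2), at 4.84 ± 2 against 377 ± 186, and so was FOXJ1, the regulator of motile cilia (−5.45 log2), at 0.711 ± 0.192 against 170.4 ± 192. SLA (3.04 log2), NEUROD6 (2.92), ISLR2 (2.88) and NEUROD2 (2.81) were higher, and 8 of 8 choroid plexus and ependyma genes were lower, over all genes and adjusted over the list alone (adjusted p = 0.155 with an estimated correlation). Limma called 7378 of 12356 genes between CP and VZ, 3627 higher and 3751 lower, and 2683 between OSVZ and VZ, 1153 higher and 1530 lower. The OSVZ count was 1757 without WT16 and 816 without WT17. With FPKM as deposited the median gene shifted by −0.453 log2 between CP and VZ and by −0.142 between OSVZ and VZ, and 24.7% and 20.6% of called genes were higher, against 49.2% and 43% with scaling.

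In fetal brain, CITED4 (ENSMMUG00000029715), a coactivator that binds CBP and p300, was at 941 and 1141 FPKM in the 2 TG animals and listed at 0 in all 4 WT animals (limma adjusted p = 1.37e-06). It was listed at 0 in all liver and muscle libraries of the set. Of 38 ribosomal protein genes 0 passed limma over all genes and 38 rose adjusted over the list alone, with a median of 0.78 log2 (camera adjusted p = 1.45e-28; adjusted p = 0.545 with an estimated correlation). RPL30 stood at 1446 ± 253 FPKM (SD, n = 2) against 630.2 ± 74.8 (SD, n = 4), with adjusted p = 0.0804. Of 48 synaptic genes 0 passed limma over all genes and 23 fell adjusted over the list alone, with a median of −0.62 (camera adjusted p = 7.54e-14; adjusted p = 0.545 with an estimated correlation). Examples were GRIN2A at −1.74, RIMS1 at −0.92 and GRIN1 at −0.69. The list mean was 5.16 log2 in TG03, 5.78 in TG04 and 5.91 to 6.22 in WT, so TG03 lay farther from WT than TG04. Of 8 genes of erythroid cells 0 passed limma over all genes, and 4 rose and 1 fell adjusted over the list alone, with a median of 1.56 (camera adjusted p = 0.0373; adjusted p = 0.545 with an estimated correlation). In the blocked fit this call ended (camera adjusted p = 0.0527). Among them HBG2, a fetal globin, was at 1145 ± 139 FPKM in TG and 138.5 ± 72.7 in WT (adjusted p = 0.119), and HBB, the adult globin, at 39.1 ± 1.07 and 264 ± 133 (adjusted p = 0.138). Limma called 4 of 13567 genes, all higher and 3 without a symbol, with 2263 at unadjusted p under 0.05. The count was 1 with the smaller pseudocount, 2 with embryonic day as a term and 153 in the blocked fit. It was 24 without TG03, 1118 without TG04, 2 without WT09 and 1 without WT10 or WT12.

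In fetal liver, TACC1 (ENSMMUG00000010152), a centrosomal protein, fell by 1.89 log2 to 4.38 ± 0.253 FPKM (SD, n = 2) from 21.4 ± 1.7 (SD, n = 4). RPL21 (ENSMMUG00000032571) rose by 3.28 log2 to 9.57 ± 0.496 from 0.181 ± 0.0662. KLK13 was at 6.02 ± 1.88 in TG and listed at 0 in all WT, and SNUPN, an importer of spliceosomal particles, was listed at 0 in TG and at 82.3 ± 23.4 in WT. Of 29 hepatocyte genes 0 passed limma over all genes and 3 fell adjusted over the list alone, with a median of −0.55 (camera adjusted p = 0.0357; adjusted p = 0.648 with an estimated correlation). With FPKM as deposited the call of hepatocyte function ended (camera adjusted p = 0.175). AFP, the fetal serum protein, was at 1165 ± 777 FPKM against 232 ± 56.6 (adjusted p = 0.295) and CYP2E1, an enzyme of mature hepatocytes, at 9.00 ± 5.26 against 160 ± 90 (adjusted p = 0.257). Of 16 erythroid genes 0 passed over all genes, and 2 rose and 1 fell adjusted over the list alone, with a median of 2.02 (camera adjusted p = 4.46e-06; adjusted p = 0.648 with an estimated correlation). HBB was at 196 ± 175 FPKM against 2011 ± 541 (adjusted p = 0.276). The liver library of TG04 had a median Spearman correlation of 0.846 with the other liver libraries. Limma called 9 of 12153 genes, 6 higher and 3 lower, 5 of them without a symbol, with 1293 at unadjusted p under 0.05. The count was 278 in the blocked fit, 2502 without TG03 and 23 without TG04.

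In fetal muscle, MYH7 (ENSMMUG00000014762), the slow myosin heavy chain, fell by 2.33 log2 to 267 ± 51 FPKM (SD, n = 2) from 1406 ± 132 (SD, n = 4), and MYL3, its light chain, by 1.77 log2 to 534 ± 121 from 1888 ± 143. AQP4, a water channel, fell by 3.05 log2 to 4.98 ± 2.61 from 48.8 ± 7.6. HMGA1 (ENSMMUG00000019529), a chromatin protein of growing cells, rose by 1.58 log2 to 82.0 ± 2.33 from 28.3 ± 1.74. HOXC10, a factor of posterior body pattern, was at 32.6 ± 10.5 in TG and listed at 0 in WT, and its neighbour HOXC9 rose by 2.30 log2. The labels name the tissue as muscle without a body site. It is therefore not known whether TG and WT muscle came from the same site, for these or the other genes. RPL21 (3.92 log2), FAM81B (2.47), CXCR4 (1.81), IER3 (1.78), TUBB6 (1.6), RPL3 (1.44) and JUND (1.42) rose. GHRL (−3.79 log2), SLC38A3 (−2.84), MPEG1 (−2.55), PFKFB1 (−2.51), SCARA5 (−2.37) and CHRDL1 (−2.12) fell, and NBPF3 was listed at 0 in TG and at 89.0 ± 9.01 in WT. All moved the same way in 2 of 2 TG animals, as the rule for naming required, at limma adjusted p of 0.047 or less.

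Of 26 adult contractile genes in muscle 5 fell, MYH7, MYL3, TNNC1 (−1.75 log2), TNNT1 (−1.66) and MYL2 (−1.58), all expressed in slow fibres, and 9 fell and 1 rose adjusted over the list alone, with a median of −0.20 (camera adjusted p = 0.0481; adjusted p = 0.706 with an estimated correlation). The call was lost in the blocked fit (camera adjusted p = 0.575). Of 15 embryonic muscle genes 0 passed limma over all genes and 8 rose adjusted over the list alone, with a median of 0.93 (camera adjusted p = 9.73e-06; adjusted p = 0.698 with an estimated correlation). MYH8, the perinatal myosin, was at 366 ± 84.2 FPKM against 63.6 ± 58.4 (adjusted p = 0.0881). MYH3, the embryonic myosin, was at 850.1 ± 65.2 against 113 ± 164 (adjusted p = 0.104), with WT12 at 359 and the other WT animals at 29.4 to 34.1. Of 38 ribosomal protein genes 1 rose over all genes, RPL3, and 38 adjusted over the list alone, with a median of 1.05 (camera adjusted p = 1.18e-27; adjusted p = 0.698 with an estimated correlation). Limma called 39 of 12384 genes, 22 higher and 17 lower. The count was 25 with FPKM as deposited, 66 with quantile scaling, 14 with the smaller pseudocount, 2 with embryonic day as a term and 906 in the blocked fit. It was 3281 without TG03, 1301 without TG04, 5 without WT09, and 7 without WT10, WT11 or WT12.

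**Figure D3:**
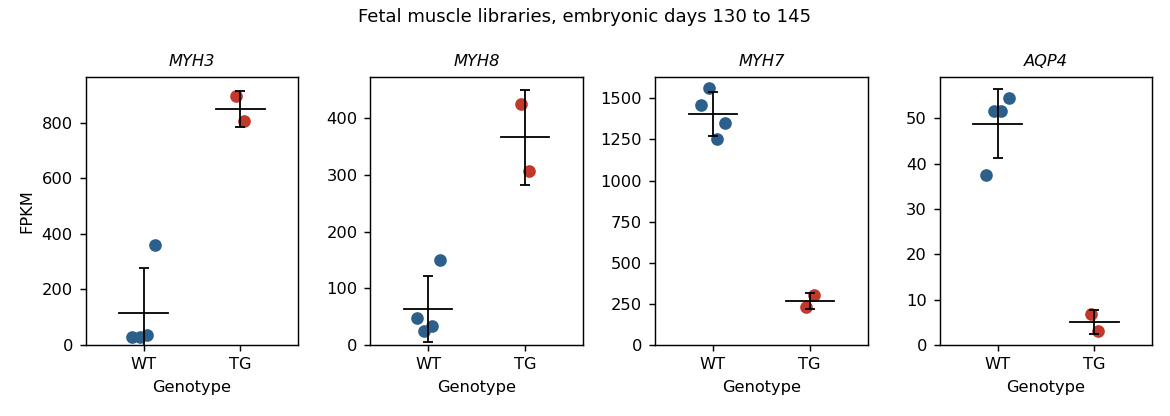
MYH3, MYH8, MYH7 and AQP4 in FPKM in the fetal muscle libraries by genotype, with points for libraries, a line for the mean and a bar for the SD. MYH7 lay at 267 ± 51 in TG and 1406 ± 132 in WT.

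A test of whether the TG minus WT difference differed between fetal tissues called 4 of 14217 genes between brain and liver: CITED4 (9.70 log2), SNUPN (7.81), MORN2 (4.09) and KLK13 (−3.16). Between brain and muscle it called 7 of 13995 genes: CITED4 (9.83), NBPF3 (5.87), AQP4 (3.36) and CHRDL1 (2.53) toward brain, and MICAL2 (−3.52), HOXC10 (−5.29) and SPHAR (−6.44) toward muscle. The brain and liver count was 2 with FPKM as deposited, 1 without the filter, 1324 without TG03, 31 without TG04 and 2 without WT12, and the brain and muscle count was 1125 without TG03 and 742 without TG04.

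At day 75, TG02 was the only TG animal, so values were compared with both WT animals and no test was run. In brain, the median of 18 astrocyte genes was 2.7 log2 lower in TG02 than the mean of WT, with 12 genes more than 1 log2 unit below both WT animals. That median lay at percentile 0 among 10000 random lists, which describes 1 animal and is no test of genotype. The WT animals differed by 0.04 on the astrocyte list. Radial glia genes (−1.34) and outer radial glia genes (−1.15) were lower in TG02 and deep layer neuron genes (0.71) higher. In liver, 40 ribosomal protein genes had a median of 0.95, with 15 higher, and CGA, a hormone subunit, was at 836 FPKM against 2.22 and 0.185. In muscle, 40 ribosomal protein genes had a median of 1.39, with 27 higher, and 27 adult contractile genes a median of −1.04, with 10 lower, where the WT animals differed by 0.66. Genes of meninges and fibroblasts had medians of −2.63 in muscle (9 lower), −1.58 in brain (7 lower) and −0.98 in liver (3 lower). Immediate early and heat shock genes had medians of −1.11 in muscle, −1.42 in brain and 0.39 in liver, and adult contractile genes one of 1.17 in liver (6 higher). PVALB, a calcium buffer of fast fibres, was at 8.15 FPKM against 618 and 905. The mitochondrial gene ATP8 was at 23.5 FPKM in brain against 11200 and 9840, and most other top genes were small RNAs listed at 0 on one side. TG02 lay beyond 1 log2 unit from both WT animals at 1408 of 15948 genes in brain (469 higher, 939 lower), 2192 of 14309 in liver (1122, 1070) and 3393 of 14910 in muscle (1867, 1526). The same count was 436 and 419 for WT04 and WT05 in brain, 504 and 597 in liver, and 660 and 734 in muscle.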

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

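The tests of whether the TG minus WT difference differed between layers or tissues were set before the files were examined. All other tests in this part were chosen after the results were seen. In the OSVZ and SVZ, genes called between animals labelled TG and WT ran along the difference between cortical plate and ventricular zone in WT: 73.7% and 72.7% of called genes followed it, against 59.7% and 61.2% of all genes. Of 276 abundant genes at least 4 times higher in WT CP than in WT VZ, 90.9% were higher in TG in OSVZ, and 92.7% of 275 in SVZ, as more cortical plate cells in these captures would give. Maturation of cells in place would give the same, so this test does not separate capture from biology. If genotype were the source, both TG09 libraries should show it. The r across genes of the md OSVZ library with this axis was 0 (Spearman's rho −0.01), so that library did not show it. The value lay between those set for the 2 outcomes and rests on 1 library, so it does not decide the source. In OSVZ the same r was 0.27 for the plain library, 0.37 for TG10, 0.55 for TG11 and −0.45 to 0.32 among WT. For the md and plain libraries, TG10, TG11 and WT it was 0.07, 0.14, 0.41, 0.52 and −0.17 to 0.17 in SVZ. In that order it was −0.03, 0.17, 0.33, 0.4 and −0.19 to 0.28 in VZ, and 0.02, −0.24, −0.26, −0.28 and −0.12 to 0.1 in CP. In CP and VZ, WT libraries of the layer entered both the axis and the TG minus WT difference. That shared part lowers r of the TG libraries in CP and raises it in VZ, but leaves the WT values without such a push. The negative values in CP and the positive values in VZ are thus in part built in.

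The counts in the layers depended on which TG09 library was used. The plain minus md difference within TG09 correlated across genes with the TG minus WT difference at E92 (r = 0.42 over the mean of 4 layers, against 0.05 to 0.17 in size for pairs of WT animals), as a difference between captures of 1 animal along the group difference would give. By layer this r was above the 4 WT pairs of the same layer in OSVZ (0.45, highest pair 0.23) and SVZ (0.16, 0.13), and within them in CP (0.36, 0.57) and VZ (0.3, 0.35). In the plain SVZ and VZ libraries, ventral forebrain genes were higher than in the md libraries by a median of 1.92 and 2.94 log2, and cortical genes differed by −5.52 and −3.82, as ventral tissue in those 2 plain libraries would give. In the plain OSVZ library the medians were 1.63 and −1.87, which ventral tissue there would also give, and in CP they were 1.26 and 0.27.

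MCPH1 was not raised in the layer libraries labelled TG. A rise as large as in the TG03 brain (1.13 log2) lay outside the intervals, whose highest upper bound was 0.59 log2. Transcripts of the added human copies may not have been counted in the layer files: in 3 of 4 layers the WT mean was at or above that of fetal brain WT, so the monkey gene was counted, which cannot tell about the human copies. Labels of animals could not be checked from MCPH1 in this set for that reason.

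Splits of the 8 layer animals into 3 and 5 were counted for how often they called at least as many genes as the labels. In OSVZ the labels called 2673 genes and 2 of 55 splits reached this (highest other 3483), in SVZ 1267 and 2 of 55 (5015). Over the 4 layers they called 3283 and 2 of 55 reached this (4919). These shares are under 0.05 and were not adjusted over the comparisons. Splits of the animals cannot separate genotype from other differences between them, such as capture or sex. The splits used the mean of the 2 TG09 libraries and were not repeated with the md library alone. In CP the labels called 6 genes and 4 of 55 splits reached this (3588), so chance cannot be excluded. In VZ they called 76 genes and 3 of 55 splits reached this, the highest being WT15, WT16 and WT17 against the rest (724). Of the 30 splits that keep 1 E76 animal in the group of 3, as the labels do, 1 reached the labels' count in VZ (highest other 58), OSVZ (7), SVZ (159) and over the 4 layers (8), and 2 did in CP (6). Whether the share in VZ lies under 0.05 therefore depends on which splits are counted. The share of 1 of 30 is the smallest that the splits within age allow. For the CP and VZ interaction, 0 genes were called and all 55 of 55 reached this (1795). The highest other split over the 4 layers set WT15, WT16 and WT17 against the rest, which with the age term is the same contrast of the E92 animals, and in CP it set TG10, TG11 and WT17 against the rest, so the E92 animals hold a structure. Exchanges of layers within WT animals gave 1 of 16 at least as large for CP against VZ (7378, highest other 2) and 1 of 16 for OSVZ against VZ (2683, highest other 0), too few for a share under 0.05.

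Of 233 groups of values searched, 14 held a library far from the others, where chance alone gives about 1 in 20 (11.7). Oxidative phosphorylation genes in OSVZ had a mean log2 of 6.08 in WT13 and 6.44 to 6.54 in the others. Outer radial glia genes in SVZ were at 4.7 in WT15 and 4.05 to 4.23 in the others. Astrocyte genes in SVZ were at 4.38 in WT13 and 5.19 to 5.44 in the others. Hypoxia genes in SVZ were at 4.49 in WT14 and 3.29 to 3.53 in the others, and in VZ at 5.01 in WT14 and 3.66 to 3.95. Ribosomal protein genes in SVZ were at 10.2 in WT13 and 9.67 to 9.72 in the others. The fetal brain library of WT10 implied 9.07 M fragments, and the others 6.62 to 6.99 M. Radial glia genes in fetal brain were at 4.47 in WT10 and 4.54 to 4.55 in the others, and intermediate progenitor genes at 4.54 in WT12 and 4.32 to 4.35. In fetal liver, WT11 had microglia genes at 5.58 (others 5.24 to 5.29) and hepatocyte genes at 9.48 (others 9.01 to 9.03). In fetal muscle, outer radial glia genes were at 3.84 in WT11 (3.86 to 3.87), microglia genes at 3.37 in WT12 (3.9 to 3.98) and erythroid genes at 6.33 in WT10 (4.99 to 5.15).

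The TG minus WT difference differed between tissues at 4 genes for fetal brain and liver and 7 genes for fetal brain and muscle. By camera it differed at 11 gene lists for CP and VZ, 11 for fetal brain and liver and 8 for fetal brain and muscle, and at 0 with an estimated correlation.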

How the results depend on the processing

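The alternatives that leave out pairs of libraries or average CP and VZ alone were chosen after the results were seen. Each comparison rests on few animals, and the effect of depth was not tested. The directions of the lists called between TG and WT held with FPKM as deposited and with quantile scaling, though some calls did not. For each value below that differs from the report's, the cause was not tested. The fits without the OSVZ or SVZ libraries of TG10 and TG11, and those with age without 2 WT libraries, leave 1 animal in a group, which is assumed to vary like the others. Beside a limma count of 0 the number in brackets is of genes at unadjusted p under 0.05. In CP (6 genes) the count was 2 with quantile scaling, 2 with a pseudocount of 0.1, 0 without the filter (4146), 1656 with the plain and 0 with the md library of TG09 (2038), 2 without the age term, 1525 at E92 alone, 1348 in the blocked fit and 0 without the CP libraries of WT15 and WT16 (2330). In OSVZ (2673) it was 1025 without the filter, 3 with the md library, 889 without the age term and 6 without the OSVZ libraries of TG10 and TG11. In SVZ (1267) it was 2903 as deposited, 530 without the filter, 2309 plain, 0 md (3931), 27 without the age term, 5978 at E92 alone, 1995 blocked and 4 without the SVZ libraries of TG10 and TG11. In VZ (76) it was 1028 as deposited, 26 with quantile scaling, 23 without the filter, 797 plain, 0 md (1813), 0 without the age term (2039) and 245 blocked. Over the 4 layers (3283) it was 2040 without the filter, 9 md, 1083 without the age term, 5095 at E92 alone and 344 for CP and VZ alone. In fetal brain (4) it was 1 with a pseudocount of 0.1, 2 with embryonic day and 153 blocked, in liver (9) 278 blocked, and in muscle (39) 25 as deposited, 66 with quantile scaling, 14 with a pseudocount of 0.1, 2 with embryonic day and 906 blocked. With age in WT, CP (2222) gave 13 without the filter and 19 without the CP libraries of WT15 and WT16. OSVZ (299) gave 107 as deposited, 186 with quantile scaling and 13 without the filter, and SVZ (3361) 12 without the SVZ libraries of WT16 and WT17. VZ (30) gave 105 as deposited, 17 with quantile scaling, 129 with a pseudocount of 0.1, 6 without the filter and 0 without the VZ libraries of WT16 and WT17 (2572). The CP and VZ interaction (0) gave 69 plain, and the fetal brain and liver interaction (4) gave 2 as deposited and 1 without the filter. The correlation with age in CP was stronger with the md library (−0.6). MCPH1 turned sign in CP with quantile scaling (−0.15) and the plain library (−0.04), and in VZ with the plain library (0.04). Camera called 205 lists and 0 with an estimated correlation. Fry called 98 lists, 68 of them among the 205 with the same direction.

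Single genes turned direction in a few fits. Without the OSVZ libraries of TG10 and TG11, C19H19orf81 stood at 0, NCAPD3 at 0.026 and PDGFRB at 0.093 log2. Without the SVZ libraries of TG10 and TG11, CDC25C stood at 0.22 and HMGB2 at 0.018. With quantile scaling RPL14 stood at −0.16 between CP and VZ in WT and 0.24 in the interaction. PFKFB3 in fetal liver ranged from −0.20 without TG04 to 3.89 without TG03.

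Leaving out 1 of 2 animals of a group (TG03, TG04, or WT13 and WT14 with age) leaves 1, assumed to vary like the others. Leaving out 1 animal at a time, the count in CP was 2601 without TG09, 2 without WT13 or WT14, 1 without TG11, WT15 or WT17, and 0 without TG10 (1450) or WT16 (2348). In OSVZ it was 3692 without TG09, 1190 without WT15, 7 without WT14, 6 without WT17, 2 without TG11, 1 without TG10 and 0 without WT16 (4013). In SVZ it was 5524 without TG09, 2 without TG11, 1 without WT17, and 0 without TG10 (3009), WT15 (3101) or WT16 (3100). In VZ it was 778 without TG09, 47 without WT15, 42 without WT16, and 0 without TG10 (1800), TG11 (1515), WT13 (2534), WT14 (2660) or WT17 (2052). Over the 4 layers it ran from 210 without TG11 and 394 without TG10 through 1082 (WT16), 1594 (WT15) and 1761 (WT17) to 5326 without TG09. Fetal brain gave 1118 without TG04, 24 without TG03, 2 without WT09 and 1 without WT10 or WT12. Liver gave 6 without WT11, 23 without TG04 and 2502 without TG03. Muscle gave 3281 without TG03, 1301 without TG04, 7 without WT10, WT11 or WT12, and 5 without WT09. Age in CP gave 2 without WT16, 7 without WT14, 12 without WT15, 14 without WT13 and 6766 without WT17. In OSVZ age gave 21 without WT13, 29 without WT16, 40 without WT17, 47 without WT14 and 2197 without WT15. In SVZ age gave 780 without WT17, 818 without WT16, 1879 without WT15, 2138 without WT13 and 3632 without WT14. In VZ age gave 11 without WT13, 13 without WT17, 16 without WT14, 140 without WT16 and 1091 without WT15. OSVZ against VZ gave 816 without WT17, 1757 without WT16 and 2245 without WT13, and CP against VZ 6317 to 7258. The CP and VZ interaction gave 406 without TG09 and 0 without TG10. The brain and liver interaction gave 2 without WT12, 31 without TG04 and 1324 without TG03, and brain and muscle 5 without WT10, 742 without TG04 and 1125 without TG03. The correlation with age ran from −0.08 (without TG09) to 0.27 in OSVZ and from −0.35 to 0.03 (without WT14) in SVZ, and held its sign in CP (−0.7 to −0.47). MCPH1 ran from −0.16 to 0.16 log2 in CP and −0.09 to 0.05 in VZ. It was −0.15 without TG09, −0.16 without WT15 or WT16 in CP, and 0 without TG10, 0.02 without TG11 and 0.05 without WT14 in VZ. In the other tissues and layers it held its sign. At day 75, with 1 WT animal instead of 2, the genes beyond 1 log2 unit were 2210 and 2299 in brain, 3252 and 3401 in liver and 4754 and 5051 in muscle, as fewer references to pass must give.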

Other observations

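Gene groups beyond those of the report moved in some tissues. In OSVZ, 5 of 14 astrocyte genes fell in TG and 6 adjusted over the list alone, with a median of −0.81 log2 (camera adjusted p = 0.0024; adjusted p = 0.577 with an estimated correlation). Of 8 interferon response genes in OSVZ 1 fell over all genes and 7 adjusted over the list alone, with a median of −0.60 (camera adjusted p = 0.0044; adjusted p = 0.577 with an estimated correlation). Without the OSVZ libraries of TG10 and TG11, an alternative chosen after seeing the data that leaves 1 TG animal (TG09) against 5 WT, both calls ended, with medians of −0.06 for astrocytes and −0.3 for interferon response. In VZ, of 19 hypoxia response genes 0 passed limma over all genes and 2 fell adjusted over the list alone, with a median of −0.69 (camera adjusted p = 0.00298; adjusted p = 0.621 with an estimated correlation). The WT library of WT14 stood apart on this list, at a mean log2 of 5.01 against 3.66 to 3.95 in the other WT animals. In fetal muscle, of 12 genes of meninges and fibroblasts 0 passed limma over all genes and 6 fell adjusted over the list alone, with a median of −0.70 (camera adjusted p = 0.00112; adjusted p = 0.698 with an estimated correlation). COL3A1, a fibrillar collagen, stood at −1.40 log2 there (adjusted p = 0.053). Of 10 macrophage and microglia genes in muscle 0 passed limma over all genes and 4 fell adjusted over the list alone, with a median of −0.64 (camera adjusted p = 0.00112; adjusted p = 0.698 with an estimated correlation).

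With age in WT, 5 of 10 oligodendrocyte precursor genes rose in OSVZ and 7 adjusted over the list alone, among them OLIG2 (2.49 log2), with a median of 1.14 (adjusted p = 0.175 with an estimated correlation). Of 14 astrocyte genes there 6 rose, and 10 rose and 1 fell adjusted over the list alone, with a median of 0.96 (adjusted p = 0.446 with an estimated correlation). In VZ, of 35 genes of G2 to M phase 0 passed limma over all genes and 32 fell with age adjusted over the list alone, with a median of −1.08 (adjusted p = 0.571 with an estimated correlation).

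The Y-linked genes EIF1AY and DDX3Y were expressed in the layer libraries of TG09, TG10, TG11, WT14 and WT16. In WT13, WT15 and WT17 they were at or near 0. All TG animals of the layers thus expressed them, and of the WT animals only WT14 at E76 and WT16 at E92. Sex and genotype were therefore not balanced in the layers. No fit held a term for sex, so the TG minus WT differences in the layers may include differences between the sexes. WT14 and WT16 would allow such a term beside genotype and age, but no such fit was run. The plain and md libraries of TG09 had Spearman correlations across genes of 0.945 in CP, 0.874 in OSVZ, 0.9 in SVZ and 0.884 in VZ.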
